A study of Mus musculus with 4 samples.

How the data were processed

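The samples were 4 sections of proximal small intestine from wild-type male C57BL/6 mice, 1 section in each of 4 groups. Per the labels, mice ate a standard diet or a GW3965 diet for 10 days, then received 200 third-stage larvae of Heligmosomoides polygyrus by gavage, and the tissue was collected on day 6 or day 14 of infection. The intestine was rolled up and frozen, and sections of 10 µm were placed on capture areas with a side of 6.5 mm for 10x Genomics Visium, in which each barcoded spot captures polyadenylated RNA from the tissue above it. A spot can hold several cells of different types. Uninfected tissue was not analysed here.

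The authors deposited, for each section, a matrix of UMI counts per gene and spot and a table of spot positions. Per the submitters' processing notes the reads were processed with Space Ranger against mm10; the version of Space Ranger and of its annotation is not given in the sources used here. The deposited values were whole numbers with different totals per section, so they were taken as raw counts with no normalization. Each matrix held 32285 genes, and its spots were exactly those marked as over tissue. No spot was removed for the section totals. Depth ran from 1127478 to 14185525 UMIs per section, and the day 14 sections were the shallower ones, so that fewer genes could be compared there. Coordinates come from the RefSeq annotation of GRCm38, in which 26259 of the 32285 genes (81.3%) were found by symbol.

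Groups were taken from the labels. The comparisons were diet at day 6 and at day 14 (GW3965 over standard) and day within each diet (day 14 over day 6). With 1 section per group no test was made. UMIs of a gene were summed over all spots of a section and divided by the section total to give CPM. A gene was compared when its pooled CPM times the smaller section total was at least 20 UMIs. It met the rule of size when the ratio was at least 2-fold, the exact conditional binomial 95% interval of the ratio excluded 1, and the CPM of all 4 spatial quadrants of one section lay above all 4 of the other. Quadrants describe the spread within a section and are not replicates. A gene with 0 UMIs on one side was given a ratio against a floor of 3 counts in that section, which is not its exact interval bound. Exact Poisson intervals were used for single CPM values and exact binomial intervals for shares of spots. Both cover counting error only, not differences between mice, sections or cutting positions.

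Before the data were examined, 42 gene lists for pathways and cell types were fixed, together with the groups, comparisons, rule of size, most alternative settings and the rule for named genes. For each list the median log2 ratio of its compared members was taken minus the median of all compared genes, where at least 3 members were compared, and placed among 10000 random lists of the same size matched on mean expression in 20 bins. The lists described in the text, and those whose spatial concentration is given, were chosen after the values of all lists had been seen. Named genes were, in each comparison, the 8 higher and 8 lower genes that met the rule of size with the most conservative fold (the interval bound nearest to 1), up to 4 compared members of each described list by the same measure, and the 8 higher and 8 lower genes set apart by diet. Mitochondrial genes, Gm and Rik gene models, immunoglobulin and T cell receptor variable segments, ribosomal protein genes and pseudogenes were left out of these ranks. Abca1, Abcg1, Abcg5, Abcg8, Srebf1, Mylip and Scd1 were always named where compared. This named 165 genes, some of which are not reported here. A gene was set apart by diet when both sections of one diet were at least 1.5-fold above both of the other, and the same count was made for the split by day and for the crossed split.

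For regions, spots were thinned to 200 UMIs, and 64, 23, 1139 and 1261 spots below that number were left out of the standard day 6, GW3965 day 6, standard day 14 and GW3965 day 14 sections. The thinned counts of all sections were log-normalized together, and 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering at resolution 0.6 were used. Mitochondrial genes, Gm42418, AY036118 and Lars2 were kept out of the clustering, a choice made after the data were seen. The neighbour graph was built in 3 ways, and the weighted exact graph, with 7 regions, was chosen after the clusters had been seen; the unweighted exact graph is kept as an alternative and the approximate graph run first is not tabulated. A region was called by a list when at least 3 of its 20 leading genes were members, a rule also set after the data were seen. Moran's I was computed over the 6 neighbouring spots of the array on spots thinned to 200 UMIs. Doublets were not called, since spots are not cells.

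Alternatives were TMM factors, median-of-ratios factors, totals without mitochondrial genes, spots of at least 200 UMIs, all sections thinned to the shallowest total, the mean of CPM per spot, sections without smooth muscle-led spots, a minimum of 50 expected UMIs, a 1.5-fold rule and no quadrant requirement. For regions they were resolutions 0.4 and 1.0 and thinning to 100 and 500 UMIs. Totals without Gm42418, AY036118 and Lars2, a count minimum on the mean CPM of both sections, and the unweighted graph were added after the data were seen. Genes left out of the totals were also left out of the genes compared. The pooled count minimum favours genes that are high in the deeper section of a comparison, which was noticed only after the day comparisons had been computed.

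The steps were tested on simulated data drawn from the real section means and totals, with 200 changed genes in each comparison. Of genes changed by 2.5-fold, 96.0% met the rule of size in the simulation of diet at day 6 (11026 genes), and 94.0% in those of diet at day 14 (5485 genes), day on standard diet (7446 genes) and day on GW3965 (6308 genes). The number of unchanged genes that met it was 5, 8, 6 and 5 in the same order, and the intervals covered the true ratio for 95.5%, 96.1%, 95.8% and 95.9% of genes. These simulations hold counting noise only. The changed genes were drawn from genes above the count minimum by a margin, and simulated quadrants did not differ in tissue. Recovery of true differences in these sections can therefore be lower. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors only.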

Results

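The series measured gene expression by position in the proximal small intestine of mice infected with Heligmosomoides polygyrus, a nematode whose larvae develop within the gut wall before the adults return to the lumen. The mice had eaten a standard diet or a diet with GW3965, a synthetic agonist of the liver X receptors (LXRs), which are sterol-sensing nuclear receptors that induce cholesterol efflux and fatty acid synthesis genes. Each of the 4 groups (standard or GW3965 diet, day 6 or day 14 of infection) held 1 section, so no difference has a replicate check, no test between groups was made and no p-value is given. Spots and parts of a section are not replicates. The day 6 sections held 8112545 UMIs over 3831 spots on standard diet and 14185525 UMIs over 4679 spots on GW3965. The day 14 sections held 1774121 UMIs over 4346 spots and 1127478 UMIs over 3478 spots. The median spot had 1530, 2492, 321 and 251 UMIs in the standard day 6, GW3965 day 6, standard day 14 and GW3965 day 14 sections. In the same order the gene model Gm42418, which overlaps ribosomal RNA sequence, took 2.99%, 1.40%, 19.6% and 27.4% of UMIs. Depth and the Gm42418 share therefore differed between the days more than between the diets. Folds are ratios of scaled UMI counts (CPM) of whole sections, and the range in parentheses after a fold is its exact 95% interval. These intervals, and the Poisson intervals of single CPM values, cover counting error only. Single-gene folds are not adjusted for the median of all genes, which is given with the gene counts of each comparison. Members of near-identical families (Reg3, Mcpt and Cma2, Defa, Sprr2a, Gstm and Gsta, H2-Q and the alpha-globins) can share reads, so their single values are uncertain. List values are log2 medians of the compared members minus the median of all compared genes. A list given as higher or lower lay outside the central 95% of matched random lists on that side unless its percentile is given. A member counted as higher or lower differed by at least 1.5-fold, unadjusted for the median of all genes, with an interval that excluded 1. That count does not use the stricter rule of size, which asks for a 2-fold difference and for all 4 quadrants of one section above all 4 of the other.

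The first question was what the agonist diet changed on the background of infection, and LXR target genes were its direct readout. Scd1, a stearoyl-CoA desaturase (chromosome 19, 44394450 to 44407709, GRCm38), had 240.5 CPM on standard diet and 6842 CPM on GW3965 at day 6, 28.4-fold (27.2 to 29.8) higher. At day 14 it had 170.2 and 15157 CPM, 89.0-fold (79.5 to 100.1) higher. The cholesterol efflux transporter gene Abca1 (chromosome 4, 53030789 to 53159988) was 22.9-fold (18.4 to 28.8) higher at day 6 and 15.2-fold (9.48 to 25.9) higher at day 14, and Abcg1 (chromosome 17, 31057694 to 31117984) was 8.55-fold (6.47 to 11.5) and 15.3-fold (7.95 to 32.8) higher. Srebf1, which encodes the lipogenic transcription factor SREBP-1 (chromosome 11, 60199084 to 60224186), was 4.96-fold (4.73 to 5.20) and 8.15-fold (6.53 to 10.3) higher. Abcg5 and Abcg8, whose products form the sterol exporter of the enterocyte apical membrane, were 2.12-fold (1.95 to 2.31) and 2.29-fold (2.13 to 2.46) higher at day 6 and 7.04-fold (4.35 to 11.9) and 6.33-fold (4.53 to 9.02) higher at day 14. Mylip, which encodes a ubiquitin ligase that degrades the LDL receptor, was 16.4-fold (6.85 to 51.1) higher at day 6, with 143 UMIs against 5, and had 16.9 CPM (10.1 to 26.3) against 1.69 CPM (0.349 to 4.94) at day 14, below the count minimum for a ratio. Of the sterol transport targets of LXR, 7 of 12 compared members were higher at day 6 and 7 of 9 at day 14, with none lower, and list values of 0.78 and 1.71. The lipogenic targets had 8 of 13 members higher and 1 lower at day 6, and 6 of 9 higher at day 14, with list values of 0.65 and 1.502. Among them Scd2 was 3.27-fold (3.18 to 3.35) and 3.76-fold (3.43 to 4.11) higher, while Me1, the malic enzyme gene, was 1.98-fold (1.87 to 2.09) lower at day 6 and 2.27-fold (1.92 to 2.69) higher at day 14. In both diet comparisons the fixed targets kept their direction under every alternative tried that gave them a value.

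**Figure D1:**
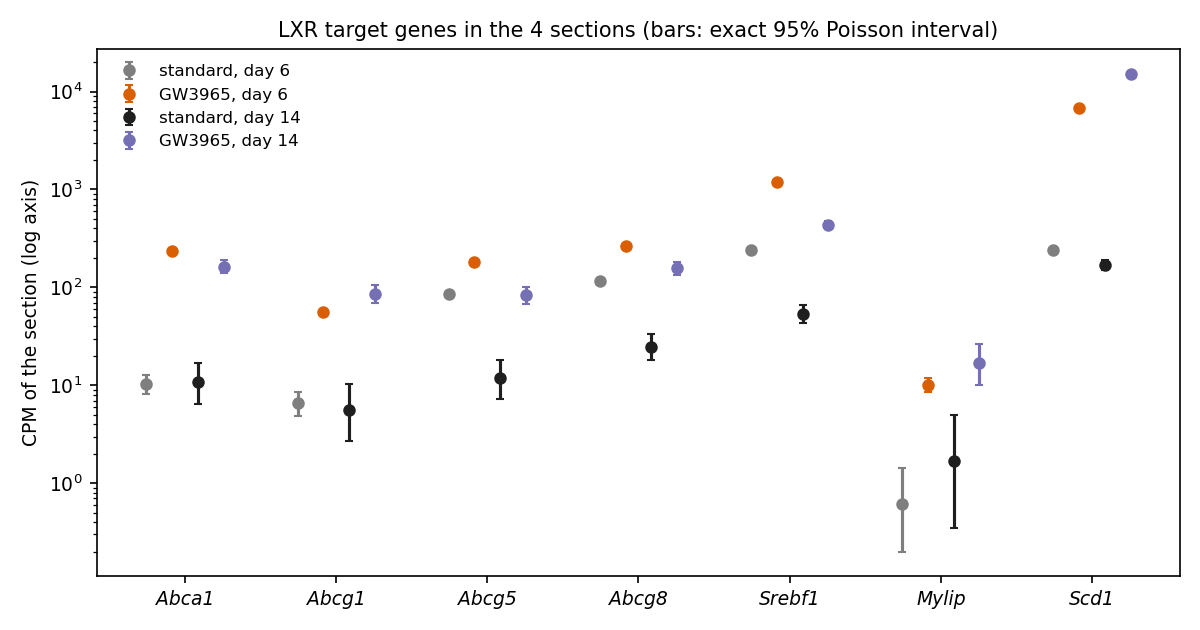
CPM of 7 LXR target genes (log axis) in each of the 4 sections, 1 section per group, with bars for the exact 95% Poisson interval of the count. Both GW3965 sections lie above both standard sections for every gene but Abcg5, whose GW3965 section at day 14 (83.4 CPM) lies close to the standard section at day 6 (85.9 CPM).

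**Figure D2:**
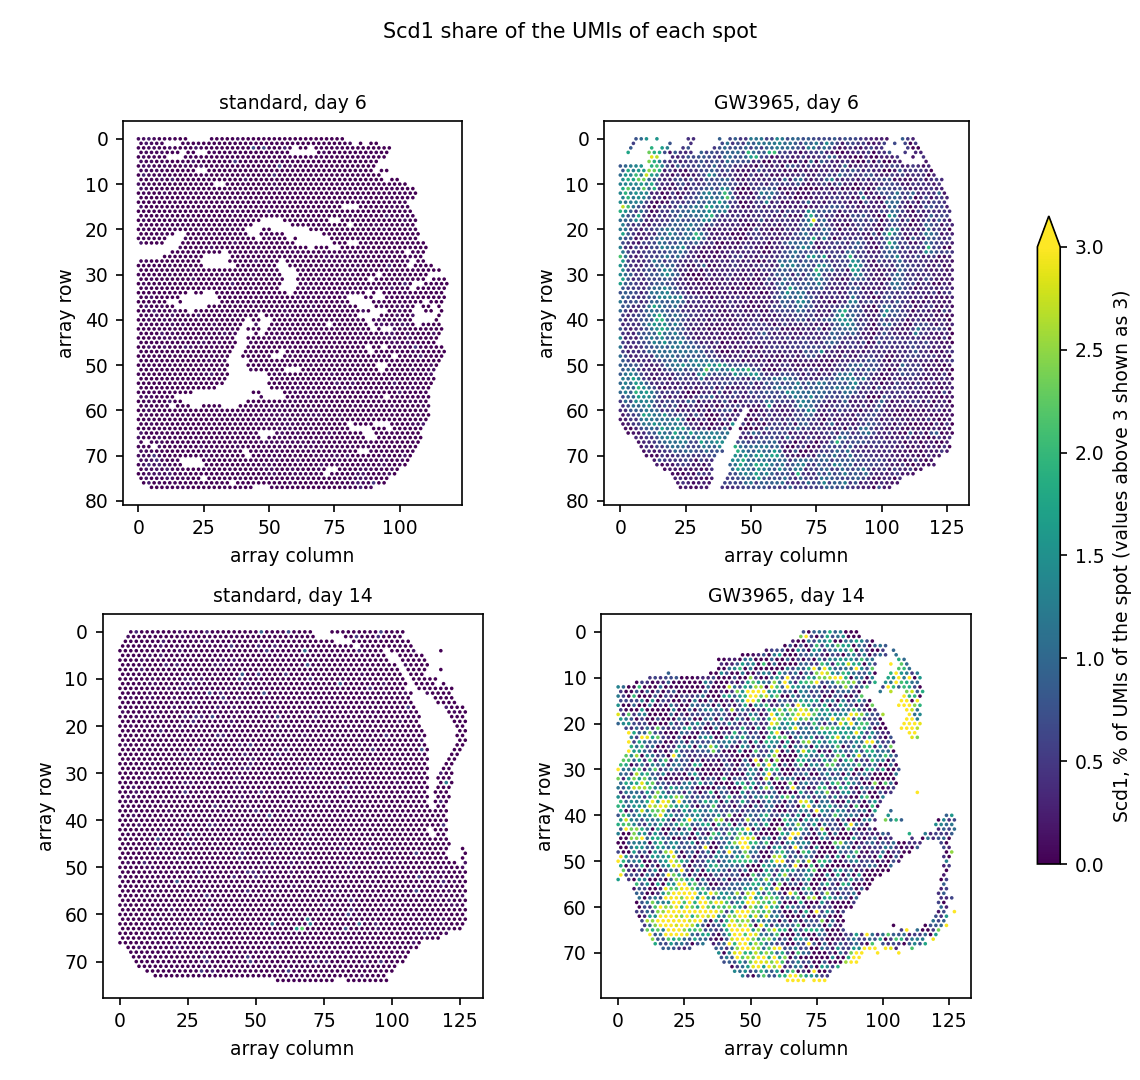
Scd1 UMIs as a percent of all UMIs of each spot over tissue, drawn at the spot's array row and column for the 4 sections, with values above 3% shown as 3. The standard sections, at 240.5 and 170.2 CPM, are dark throughout, and the GW3965 sections, at 6842 and 15157 CPM, show Scd1 over most of the tissue with brighter patches.

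At day 6 the other genes furthest above the standard section encoded antimicrobial and interferon-linked proteins. Reg3b and Reg3g, genes of bactericidal or bacteria-binding C-type lectins of the epithelium (chromosome 6, 78370885 to 78373466 and 78466269 to 78468874), were 25.5-fold (23.5 to 27.7) and 19.0-fold (16.9 to 21.6) higher on GW3965. Nos2, the inducible nitric oxide synthase gene, had 88 UMIs against 1, a ratio of 50.3-fold (8.80 to 2010.1), and Ubd, a ubiquitin-like modifier gene induced by interferon, was 5.97-fold (5.11 to 7.01) higher. In the antimicrobial villus list, 6 of 13 members were higher and 3 lower (list value 0.43), Gsdmc2 being 3.98-fold (2.76 to 5.84) lower. With each spot weighted equally that list value was 0.024. Of the interferon-induced genes, 19 of 24 were higher and 1 lower (list value 0.78): Cxcl9, a T cell-attracting chemokine gene, was 4.49-fold (2.98 to 7.03) higher, Zbp1 2.42-fold (2.10 to 2.81), Iigp1 2.37-fold (2.04 to 2.76) and Igtp 2.18-fold (1.96 to 2.44). All 7 MHC class II genes were higher (list value 1.28). H2-DMb1 was 2.79-fold (2.33 to 3.35), H2-Eb1 2.63-fold (2.28 to 3.05), H2-Ab1 2.53-fold (2.31 to 2.79) and Cd74, the invariant chain gene, 2.5-fold (2.35 to 2.66) higher. B cell and follicle genes went with them, with 8 of 9 members higher (list value 1.27): Cr2 was 4.96-fold (2.13 to 14.1), Cd22 4.67-fold (1.999 to 13.3) and Ms4a1 3.46-fold (2.06 to 6.18) higher. With each spot weighted equally the B cell and follicle value was 0.70. Of the members counted as higher, 7 interferon-induced genes and 5 MHC class II genes met the rule of size, and no B cell and follicle gene did.

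Proliferation genes and crypt and stem genes were also higher on GW3965 at day 6, and Paneth cell genes were lower. Of the proliferation genes, 13 of 18 were higher and none lower (list value 0.64). Cdk1 was 2.81-fold (2.43 to 3.27), Hmgb2 2.11-fold (1.91 to 2.33), Ccnb1 1.99-fold (1.60 to 2.48) and Mki67 1.81-fold (1.59 to 2.07) higher. Crypt and stem genes had 5 of 11 members higher (list value 0.44), Olfm4 being 2.01-fold (1.84 to 2.21), Cdca7 1.58-fold (1.29 to 1.95) and Slc12a2 1.53-fold (1.39 to 1.70) higher. Prom1, at 1.47-fold (1.24 to 1.74) higher, was below the 1.5-fold limit of that count. With each spot weighted equally the proliferation value was 0.30 and the crypt and stem value 0.21. The Paneth cell list was lower (value -0.66, 3 of 10 members lower), with Ang4 2.89-fold (2.47 to 3.38) and Defa3 2.23-fold (1.80 to 2.77) lower. Defa17 at 1.46-fold (1.35 to 1.58) and Itln1 at 1.46-fold (1.35 to 1.57) lower were below the 1.5-fold limit of that count. The rule of size was met by 2 of the proliferation genes, 1 of the crypt and stem genes and 2 of the Paneth genes so counted.

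Detoxification genes were lower on GW3965 at day 6. The xenobiotic metabolism list had 10 of 15 members lower and 1 higher (list value -1.04). The glutathione transferase gene Gstm1 was 8.81-fold (8.17 to 9.52), the cytochrome P450 gene Cyp3a11 7.09-fold (6.69 to 7.51), the glucuronosyltransferase gene Ugt2b5 5.13-fold (4.72 to 5.59) and Gstm3 3.98-fold (3.70 to 4.28) lower. The other genes furthest below the standard section were Cbr3, a carbonyl reductase gene, at 23.2-fold (17.7 to 30.8), the carboxylesterase gene Ces1g at 16.7-fold (11.2 to 26.1), Gsta2 at 15.6-fold (12.6 to 19.6), Slc5a4b at 12.8-fold (11.4 to 14.4), the gluconeogenic enzyme gene Pck1 at 9.37-fold (8.33 to 10.6) and Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, at 7.05-fold (6.57 to 7.58). Mitochondrially encoded transcripts were 1.47% of UMIs in the GW3965 section and 3.50% in the standard section. Enterocyte genes as a list were lower in the same comparison (value -0.40, 2 of 16 members lower and 1 higher). Cholesterol synthesis and uptake genes were lower as a list (value -0.33, 6 of 23 members lower and 1 higher). Msmo1 was 2.25-fold (2.15 to 2.35), Fdft1 1.85-fold (1.59 to 2.14), Sqle 1.83-fold (1.65 to 2.04) and Idi1 1.82-fold (1.67 to 1.97) lower. Of the members counted as lower, 7 xenobiotic metabolism genes and 1 cholesterol gene met the rule of size.

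Type 2 and wall-associated genes were lower on GW3965 at day 6. The type 2 epithelial response list had 5 of 11 members lower and 1 higher (value -0.66), with Pla2g4c, a phospholipase gene, at 5.02-fold (4.03 to 6.30), Ccl24, an eosinophil chemokine gene, at 4.97-fold (4.32 to 5.73) and Sprr2a3 at 3.06-fold (2.001 to 4.75). That list value was -0.30 at a minimum of 50 expected UMIs. Several lists share members, so their values are not independent in any comparison. The type 2 epithelial response list shares Ang4 and Itln1 with the Paneth cell list and Ccl24 with the granuloma list. The extracellular matrix list shares Col1a1, Col1a2 and Col3a1 with the fibroblast list, and Fn1 and Mmp13 with the granuloma list. Fabp1 and Fabp2 are on both the enterocyte and the fat absorption list. Genes of alternatively activated macrophages and granulomas had 6 of 12 members lower and 1 higher (value -0.77). Arg1 was 4.46-fold (3.16 to 6.40), Mrc1 2.53-fold (2.17 to 2.96) and Clec10a 2.27-fold (1.65 to 3.15) lower. All 14 smooth muscle genes were lower (value -1.12), Tagln by 2.36-fold (2.11 to 2.64), Synm by 2.29-fold (2.03 to 2.57), Cnn1 by 2.20-fold (2.04 to 2.38) and Myh11 by 2.13-fold (2.004 to 2.26), but none of them met the rule of size. Enteric neuron and glia genes (value -0.85, 5 of 8 lower and 1 higher) were lower. Elavl4 was 2.35-fold (1.42 to 3.94), Snap25 2.05-fold (1.40 to 3.01) and Stmn2 1.84-fold (1.37 to 2.47) lower. Extracellular matrix genes (value -0.49, 4 of 19 lower and 2 higher) were lower. Mmp14 was 5.17-fold (4.14 to 6.49), Mmp3 1.75-fold (1.42 to 2.15) and Timp1 1.60-fold (1.36 to 1.89) lower. Col1a2, at 1.46-fold (1.36 to 1.57) lower, was below the 1.5-fold limit of that count. Of the members counted as lower, 3 of the type 2 list and 1 each of the granuloma, enteric neuron and extracellular matrix lists met the rule of size. With each spot weighted equally the extracellular matrix value was -0.80. Without the spots led by smooth muscle genes the values turned for smooth muscle (0.11), enteric neuron and glia (0.87), extracellular matrix (0.12) and granuloma genes (0.048), and for Tagln, Synm, Cnn1, Myh11, Snap25, Stmn2, Mmp3, Timp1 and Col1a2.

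Over all 11021 genes compared at day 6, 202 met the rule of size as higher on GW3965 and 108 as lower, and the median log2 ratio of all genes was 0.11. The split depended on the scaling: 124 higher and 141 lower with TMM factors, 112 and 147 with median-of-ratios factors (which moved the median of all genes by -0.12), and 170 and 142 with each spot weighted equally. Without the smooth muscle-led spots it was 385 and 98.

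At day 14 the LXR targets were accompanied on GW3965 by genes of lipid handling. Fat absorption and chylomicron genes had 8 of 16 members higher and 1 lower (value 0.89), with the fatty acid transporter gene Cd36 3.40-fold (2.08 to 5.70) higher, the fatty acid-binding protein genes Fabp2 2.33-fold (2.21 to 2.47) and Fabp1 1.74-fold (1.59 to 1.90), and the apolipoprotein gene Apoc2 1.64-fold (1.52 to 1.76). Fatty acid oxidation genes and other PPAR targets had 4 of 11 members higher and none lower (value 0.56): Acot1 was 8.85-fold (4.13 to 21.7), Ehhadh 3.04-fold (2.18 to 4.27) and Acaa2 2.42-fold (1.90 to 3.11) higher. The remaining genes furthest above the standard section were H2-Q10, a class I MHC gene, at 12.7-fold (10.05 to 16.3), Hsd17b11, a lipid droplet-associated dehydrogenase gene, at 7.50-fold (6.78 to 8.31), the peroxisomal thiolase gene Acaa1b at 6.94-fold (6.33 to 7.62) and Tm4sf4 at 5.70-fold (4.58 to 7.14). Xenobiotic metabolism genes, lower at day 6, had 6 of 11 members higher and 1 lower at day 14 (value 1.03). Cyp2c55 was 5.65-fold (3.66 to 9.01), Ces2a 4.64-fold (3.79 to 5.70), Gstm1 4.30-fold (2.88 to 6.58) and Cyp2c66 3.79-fold (2.38 to 6.17) higher. That list value was 1.62 with the mean CPM of both sections in the count minimum. The enterocyte list had a value of 0.23 at percentile 91.74. Mitochondrially encoded transcripts were 3.99% of UMIs in the GW3965 section and 1.93% in the standard section. The cholesterol synthesis and uptake list had a value of -0.15 at percentile 11.95, with 5 of 14 members lower and 1 higher: Sqle, Idi1 and the cholesterol uptake gene Npc1l1 were 2.60-fold (1.60 to 4.42), 2.04-fold (1.32 to 3.24) and 1.77-fold (1.61 to 1.95) lower and Insig1 was 2.87-fold (1.93 to 4.33) higher. The rule of size was met by 2 fat absorption, 4 fatty acid oxidation and 4 xenobiotic metabolism genes counted as higher, and by no cholesterol gene counted as lower.

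Mast cell protease and mucosal defence genes were lower on GW3965 at day 14. Mcpt1 and Mcpt2, proteases of mucosal mast cells (chromosome 14, 56017964 to 56020391 and 56021584 to 56044635), were 25.2-fold (12.6 to 58.8) and 16.3-fold (9.61 to 30.2) lower, with 8 UMIs against 317 and 14 against 360, and the mast cell chymase gene Cma2 was 20.02-fold (10.01 to 46.9) lower. The type 2 epithelial response list, which holds Mcpt1 and Mcpt2, had a value of -0.24 at percentile 6.24, with 4 of 11 members lower and none higher, Pla2g4c being 2.44-fold (2.17 to 2.75) and the goblet cell gene Clca1 1.60-fold (1.38 to 1.86) lower. It was -0.37 both with all sections thinned to the shallowest total and at a minimum of 50 expected UMIs. In the antimicrobial villus list, 7 of 10 members were lower and 1 higher (value -0.84): the epithelial oxidase gene Duox2 was 7.10-fold (5.57 to 9.16) lower, its maturation factor gene Duoxa2 6.85-fold (6.31 to 7.45), Reg3b 5.20-fold (4.04 to 6.77) and Reg3g 3.93-fold (2.06 to 8.24). The remaining genes furthest below the standard section were Rexo2, with 2 UMIs against 52 and a ratio of 16.5-fold (4.35 to 140.1), and Hmox1, the heme oxygenase 1 gene, which had 0 UMIs against 59. Hmox1 was 12.5-fold lower against a floor of 3 UMIs, with an exact log2 interval bound of -3.3. Tuft cell genes were lower (value -0.88, 4 of 5 members). Lrmp was 2.91-fold (1.54 to 5.98), Ptgs1 2.29-fold (1.55 to 3.48) and Cd24a 1.86-fold (1.75 to 1.98) lower. Proliferation genes were lower too (value -0.44, 9 of 10 members). Tyms was 2.996-fold (1.67 to 5.78), Ccna2 2.51-fold (1.56 to 4.21), Birc5 1.90-fold (1.58 to 2.30) and Mki67 1.74-fold (1.24 to 2.46) lower. The interferon-induced list had a value of -0.18 at percentile 16.85, Zbp1 being 4.11-fold (2.28 to 8.03), Oasl2 1.71-fold (1.19 to 2.498) and Ifit1 1.504-fold (1.16 to 1.97) lower. That list value ran from -0.46 with each spot weighted equally to -0.031 with spots of at least 200 UMIs. Of the members counted as lower, 4 antimicrobial, 3 type 2, 3 tuft, 2 proliferation and 1 interferon-induced gene met the rule of size.

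Smooth muscle genes were lower on GW3965 at day 14 as well (11 of 13 members, value -0.77). Cnn1 was 2.82-fold (2.12 to 3.79), Synm 2.48-fold (1.94 to 3.21), Flna 2.39-fold (2.19 to 2.60) and Myh11 2.09-fold (1.86 to 2.37) lower. Enteric neuron and glia genes were lower too (value -0.72, 2 of 3). Uchl1 was 2.34-fold (1.33 to 4.36) and Stmn2 2.05-fold (1.08 to 4.17) lower. With each spot weighted equally the enteric neuron and glia value was -0.44. Genes of gastric epithelium and of Brunner glands, which lie at the proximal end of the small intestine, were also lower (value -1.55, 3 of 4 members). Tff1 was 5.93-fold (2.56 to 16.8), Gkn1 4.54-fold (2.05 to 11.9) and Pgc 2.95-fold (1.64 to 5.69) lower. The rule of size was met by 6 of the smooth muscle genes counted as lower, no enteric neuron and glia gene and 1 gene of the Brunner gland list. Over all 5439 genes compared at day 14, 50 met the rule of size as higher on GW3965 and 243 as lower, with a median log2 ratio of -0.32 over all genes. That split depended on the scaling: TMM factors moved the median by 0.32 and gave 86 higher and 62 lower, median-of-ratios factors moved it by 0.34 and gave 94 and 52, and totals without Gm42418, AY036118 and Lars2 moved it by 0.15 and gave 58 and 114.

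**Figure D3:**
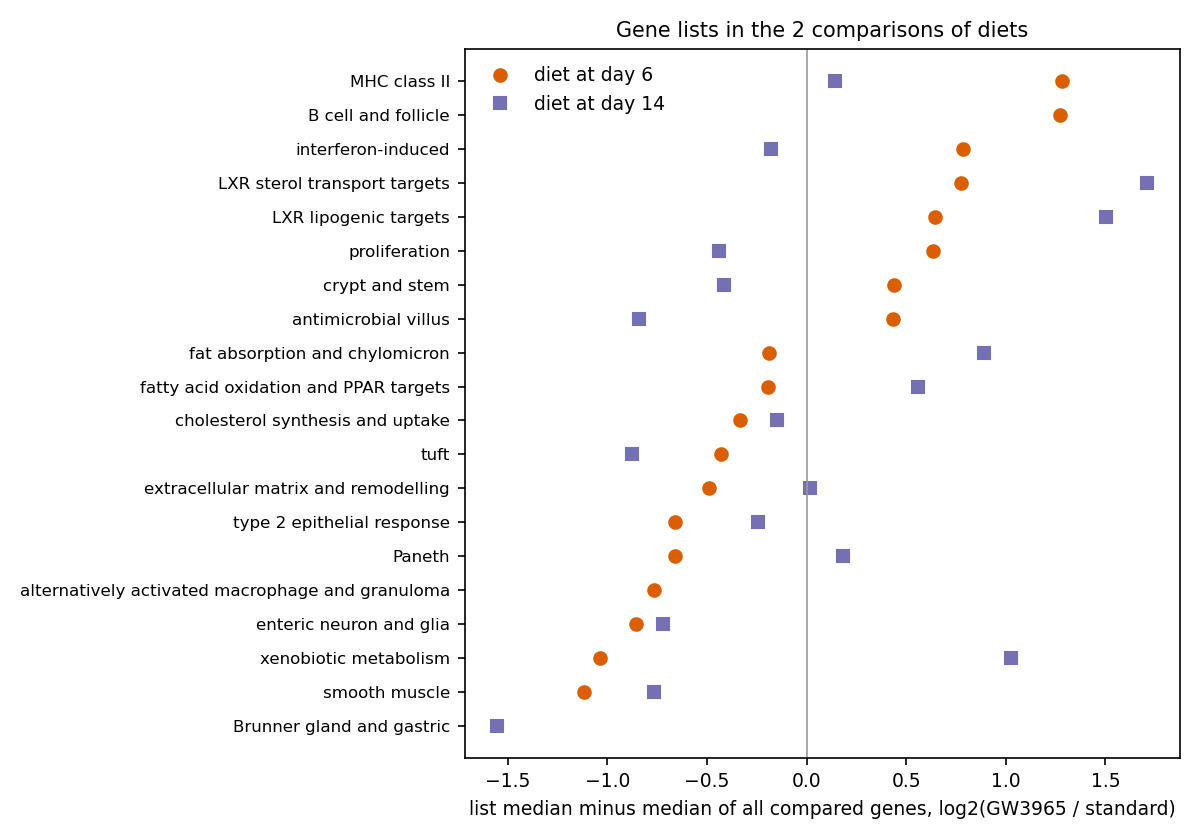
List values for 20 gene lists: the median log2 ratio (GW3965 over standard) of a list's members minus that of all compared genes, at day 6 (circles) and day 14 (squares), 1 section per group, with no marker where fewer than 3 members were compared. Both LXR lists lie above 0 at both days, smooth muscle and enteric neuron lists lie below 0 at both, and xenobiotic metabolism lies at -1.04 at day 6 and at 1.03 at day 14.

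Few genes were set apart by diet in all 4 sections. Of 6000 genes compared over the 4 sections, 13 were at least 1.5-fold higher in both GW3965 sections than in both standard sections and 18 were lower, 31 in all. The crossed split sets the standard day 6 and GW3965 day 14 sections against the other two, so it collects genes whose diet difference went in opposite directions at the 2 days and is no measure of chance. It gave 12 and 10, 22 in all. The number lower with diet was 8 with TMM factors, 11 with median-of-ratios factors, 6 without smooth muscle-led spots and 29 with all sections thinned to the shallowest total. With mitochondrial genes left out of the totals, and so of the compared genes, the crossed split gave 3 and 6. Some genes of that split were themselves mitochondrial: mt-Co2 had 3375 and 2577 CPM in the standard day 6 and GW3965 day 14 sections. It had 1264 and 912 CPM in the GW3965 day 6 and standard day 14 sections. The crossed split gave 20 and 2 with TMM factors, 14 and 21 without smooth muscle-led spots and 14 and 44 thinned. The 8 genes furthest above by their lowest GW3965 value over their highest standard value were Scd1 (28.4-fold), Abca1 (15.2-fold), Abcg1 (8.55-fold), Ubd (3.19-fold), Clu (2.65-fold), Srebf1 (1.81-fold), Scd2 (1.79-fold) and H2-Q10 (1.68-fold), 5 of which are on the fixed LXR lists. Clu was also the first leading gene of a group of spots picked out by lymphoid genes, described below. On GW3965 and standard diet that group held 6.01% and 2.71% of the grouped spots at day 6 and 2.53% and 0.34% at day 14. Whether Clu followed lymphoid tissue was not tested. The 8 furthest below were Cbr3 (2.33-fold), Cd59a (2.15-fold), Igfbp5 (2.15-fold), Tagln (1.88-fold), Tpm2 (1.82-fold), Pdlim3 (1.78-fold), Cnn1 (1.76-fold) and Plod2 (1.76-fold), of which Tagln, Tpm2 and Cnn1 are smooth muscle genes. Across the 5413 genes compared at both days, the log2 diet ratios of day 6 and day 14 had a Pearson correlation of 0.038 and a Spearman correlation of -0.016. These correlations are across genes, which are not independent replicates, and the 2 comparisons share no section. By the rule of size 7 genes were higher at both days where independent lists would share 0.369, 3 were lower at both against 3.18, and 15 went in opposite directions against 2.42.

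Grouping the spots of all sections by expression gave 7 regions. Their sizes are no measure of the amount of a tissue in a section, since their leading genes differed with day or diet or they were drawn mostly from 1 day. The smooth muscle-led spots above are the region led by Cnn1, Des, Tagln and Acta2. They were 8.20% (exact binomial interval 7.35 to 9.12) and 2.21% (1.81 to 2.68) of the spots grouped in the standard and GW3965 sections at day 6, and 5.61% (4.84 to 6.47) and 3.20% (2.51 to 4.02) at day 14. Under the other settings they ran from 8.68% to 11.5% and from 1.87% to 4.83% at day 6, and from 5.39% to 12.9% and from 3.20% to 8.14% at day 14. These shares rest on genes that were themselves lower on GW3965, so they are no separate measure of the amount of muscle. Within the smooth muscle-led spots at day 6, 103 on GW3965 and 309 on standard diet, the LXR sterol transport list had a value of 1.005, the interferon-induced list 0.72 and Scd1 a log2 ratio of 5.22. Proliferation had a value of 0.084 there (percentile 71.98), crypt and stem -0.07 (38.68) and cholesterol synthesis and uptake 0.26 (96.07), where the whole sections gave 0.64, 0.44 and -0.33. MHC class II had 1.004 there, xenobiotic metabolism -0.39, type 2 epithelial response -0.83, Paneth -0.83 and extracellular matrix -0.61. Scd1 itself, which differed with diet, is among the genes that led the region of Anxa10, Scd1 and Ada. Within that region, with 555 and 285 spots, the MHC class II list had a value of 2.22, proliferation 1.20 and xenobiotic metabolism -1.36. Those spots also differed in the crypt and stem list (1.03, percentile 99.84) and the enterocyte list (-0.44, percentile 0.54). They did not hold like tissue, so values within the region do not remove differences in tissue. Of lists that were lower in the whole section, type 2 epithelial response had 0.013 there (percentile 51.5), Paneth 0.021 (54.8), smooth muscle 0.38 (95.58) and extracellular matrix 0.53 (97.12). Moran's I, which is higher the more alike neighbouring spots are, was computed on spots thinned to 200 UMIs. For smooth muscle genes it was 0.511 in the standard and 0.153 in the GW3965 section at day 6, and 0.379 and 0.228 at day 14. For LXR lipogenic targets it was 0.041 and 0.142 at day 6 and 0.039 and 0.336 at day 14, for alternatively activated macrophage and granuloma genes 0.268 and 0.060, then 0.031 and 0.002, and for B cell and follicle genes 0.060 and 0.302, then 0.017 and 0.085. Paneth genes gave 0.264 and 0.046, then 0.299 and 0.319, and villus tip genes 0.201 and 0.202, then 0.297 and 0.376. The levels differed too: in the thinned spots LXR lipogenic targets had 1606 and 9248 UMIs at day 6 and 893 and 7264 at day 14. At day 6 smooth muscle genes had 1736 and 875, granuloma genes 289 and 130 and B cell genes 41 and 128. Paneth genes at day 14 had 1984 and 1408. All these sums are over 3767 and 4656 spots at day 6 and 3207 and 2217 at day 14, so they are not levels per spot. Of the day 14 spots, 34.6% and 32.0% held a Paneth UMI. A change of level and a change of spatial pattern therefore cannot be told apart by Moran's I. At day 14 the order of the diets turned with the thinning depth for 3 of these lists. In the standard and GW3965 sections, granuloma genes had 0.054 and 0.100 at 500 UMIs, B cell genes 0.046 and 0.030 at 100 UMIs and Paneth genes 0.304 and 0.194 at 500 UMIs.

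The second question was how the tissue differed between day 14 and day 6 of infection within each diet. On standard diet, mast cell protease, type 2 and oxidase genes were higher at day 14. Cma2 was 192-fold (87.0 to 528), Mcpt1 132-fold (72.7 to 267) and Mcpt2 68.6-fold (45.4 to 108) higher, and the type 2 epithelial response list had 7 of 11 members higher and none lower (value 1.74), Pla2g4c being 20.04-fold (17.7 to 22.7) and Ang4 6.44-fold (5.68 to 7.31) higher. In the antimicrobial villus list (value 2.44, 7 of 10 higher and 2 lower), Duoxa2 was 58.6-fold (53.6 to 64.2), Duox2 25.7-fold (21.5 to 30.9), Gsdmc2 15.5-fold (12.3 to 19.6) and Gsdmc4 5.47-fold (4.76 to 6.28) higher. Tuft cell genes (value 2.15, all 3 compared members) were higher. Cd24a was 6.67-fold (6.35 to 7.02) and Ptgs1 2.22-fold (1.77 to 2.78) higher. Paneth cell genes (value 1.92, 7 of 8) were higher. Pnliprp2 was 4.17-fold (3.28 to 5.30), Defa17 3.74-fold (3.44 to 4.08) and Itln1 3.23-fold (2.96 to 3.52) higher. Villus tip genes were higher (value 0.98, 5 of 9, with 1 lower). The nucleoside transporter gene Slc28a2 was 12.4-fold (11.6 to 13.3), Nt5e 12.02-fold (8.92 to 16.4), the adenosine deaminase gene Ada 3.23-fold (3.12 to 3.34) and Neat1 1.78-fold (1.70 to 1.87) higher. That list value was 0.60 at a minimum of 50 expected UMIs. Extracellular matrix genes (value 1.49, 9 of 15 higher and 2 lower) were higher. Loxl2 was 6.46-fold (5.13 to 8.14), Mmp10 5.87-fold (4.61 to 7.50) and Mmp14 3.96-fold (3.35 to 4.66) higher. Timp1 was 30.6-fold (8.40 to 254) lower, with 2 UMIs at day 14. Fibroblast genes (value 1.20, 6 of 11 higher and 2 lower) were higher. Col3a1 was 2.69-fold (2.19 to 3.29), Col6a1 2.51-fold (2.15 to 2.92), Col1a2 2.36-fold (2.16 to 2.59) and Col1a1 2.30-fold (2.12 to 2.48) higher. Without the smooth muscle-led spots the extracellular matrix, fibroblast and smooth muscle values were 2.39, 2.40 and 1.08. The smooth muscle list had a value of 0.18 at percentile 83.4, with Flna 2.84-fold (2.70 to 2.98), Myh11 2.28-fold (2.12 to 2.45) and Synm 2.20-fold (1.92 to 2.52) higher and Acta2 1.48-fold (1.34 to 1.64) lower, Acta2 turning to a log2 ratio of 0.62 without smooth muscle-led spots. Among the other genes furthest above were H2-M2 at 82.3-fold (36.6 to 229) and the globin gene Hba-a2 at 33.8-fold (27.3 to 42.3). Of the members counted as higher, 3 fibroblast genes, 3 villus tip genes and 1 smooth muscle gene met the rule of size. The heat shock and dissociation list, fixed as a sign of RNA quality, lay above the median of all genes (value 0.76, 3 of 8 members higher and 1 lower).

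Absorptive and metabolic genes were lower at day 14 on standard diet. Enterocyte genes had 14 of 15 members lower (value -2.02). The lactase gene Lct was 12.1-fold (10.2 to 14.6), the sucrase-isomaltase gene Sis 8.85-fold (8.21 to 9.54), Fabp1 12.3-fold (11.5 to 13.1) and Fabp2 9.43-fold (9.03 to 9.84) lower. All 15 compared xenobiotic metabolism genes were lower (value -2.61). Ugt2b5 was 52.3-fold (27.5 to 114), Cyp3a25 28.2-fold (18.9 to 44.1), Gstm1 26.0-fold (18.6 to 37.6) and Cyp2b10 23.0-fold (15.04 to 37.3) lower. The remaining genes furthest below were Slc5a4b at 104-fold (44.5 to 320.2), Ces1f at 30.9-fold (19.5 to 52.3), Mgst1 at 26.7-fold (15.9 to 49.0), Adh1 at 24.5-fold (19.2 to 31.8) and Gsta3, with 0 UMIs against 388. Gsta3 was 28.3-fold lower against a floor of 3 UMIs, with an exact log2 interval bound of -4.517. Cholesterol synthesis and uptake genes had 20 of 22 members lower and 1 higher (value -1.26). Insig1 was 9.90-fold (7.24 to 13.9), Hsd17b7 7.69-fold (3.48 to 21.2) and Dhcr7 6.56-fold (4.06 to 11.4) lower. Fatty acid oxidation genes had 15 of 16 lower (value -1.57). Pdk4 was 19.6-fold (6.64 to 95.7), Acot1 10.8-fold (5.44 to 25.2), Cpt2 9.66-fold (6.34 to 15.5) and Acaa2 6.19-fold (5.12 to 7.55) lower. Fat absorption genes had 13 of 16 lower (value -1.31). Acsl5 was 4.87-fold (4.29 to 5.56) and Dgat2 4.73-fold (4.05 to 5.57) lower. Alternatively activated macrophage and granuloma genes had 6 of 8 lower and 1 higher (value -2.02): the chemokine genes Ccl8, Ccl7 and Ccl2 were 15.9-fold (6.15 to 58.8), 7.13-fold (4.13 to 13.5) and 5.88-fold (2.93 to 13.8) lower, and the arginase gene Arg1 had 1 UMI against 120, a ratio of 26.2-fold (4.62 to 1045). That list value was 0.22 without the smooth muscle-led spots, and 1 of the members counted as lower met the rule of size. Among the LXR targets, Abcg5 was 7.26-fold (4.71 to 11.8), Abcg8 4.71-fold (3.48 to 6.53) and Srebf1 4.49-fold (3.65 to 5.58) lower, and Scd1 was 1.41-fold (1.251 to 1.60) lower, a difference that turned to a log2 ratio of 0.03 with each spot weighted equally. The LXR sterol transport and lipogenic lists had values of -0.545 (percentile 15.59) and -0.20 (34.29). Of 7381 genes compared, 635 met the rule of size as higher at day 14 and 1686 as lower, with a median log2 ratio of -0.29 over all genes. Totals without Gm42418, AY036118 and Lars2 moved that median by 0.28 and gave 925 higher and 1131 lower, and weighting each spot equally moved it by -0.19.

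On GW3965, several of the same groups were higher at day 14 than at day 6. Paneth cell genes (value 2.93, 5 of 6 higher) were higher. Ang4 was 16.3-fold (13.8 to 19.3), Itln1 5.45-fold (4.97 to 5.96), Defa17 4.97-fold (4.51 to 5.48) and Defa30 3.84-fold (3.52 to 4.18) higher. Extracellular matrix genes (value 2.11, 8 of 13 higher and 3 lower) were higher. Mmp14 was 29.4-fold (23.3 to 37.1), Loxl2 10.6-fold (8.38 to 13.4) and Col1a1 3.23-fold (2.95 to 3.53) higher. Timp1 was 24.3-fold (4.33 to 964) lower, with 1 UMI at day 14. Villus tip genes (value 1.72, 5 of 8) were higher. Slc28a2 was 7.03-fold (6.56 to 7.53), Ada 2.53-fold (2.46 to 2.61), Enpp3 2.31-fold (2.13 to 2.501) and Neat1 1.95-fold (1.83 to 2.08) higher. Tuft cell genes had a value of 2.04 (2 of 3 higher). Cd24a was 4.62-fold (4.33 to 4.92) higher. The type 2 epithelial response list (value 1.44, 4 of 8 higher and 1 lower) was higher. Pla2g4c was 41.3-fold (33.3 to 51.6) and Ccl24 3.08-fold (2.31 to 4.04) higher. That list value was 0.40 at a minimum of 50 expected UMIs and 2.40 with spots of at least 200 UMIs. Smooth muscle genes stood above the median of all genes (value 0.76), with 3 of 13 members higher and 2 lower: Flna was 2.38-fold (2.19 to 2.59), Myh11 2.32-fold (2.06 to 2.60) and Synm 2.03-fold (1.58 to 2.57) higher. Acta2 had a log2 ratio of -0.57 (-0.83 to -0.32), which did not reach the 1.5-fold limit of that count. Among the other genes furthest above were Ghdc at 53.7-fold (39.6 to 74.1), Rgs7bp at 51.8-fold (39.6 to 68.6), Trim12c at 51.4-fold (46.0 to 57.5), the beta-carotene oxygenase gene Bco1 at 36.0-fold (33.3 to 39.0) and Lars2 at 34.6-fold (33.2 to 35.9), whose counts moved with the Gm42418 share. The heat shock and dissociation list lay above the median of all genes here too (value 0.97), but its own median log2 ratio was 0.16 (2 of 8 members higher and 2 lower).

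Antimicrobial, interferon-linked and proliferation genes that were high on GW3965 at day 6 were lower on GW3965 at day 14. With a median log2 ratio of -0.81, most compared genes had a ratio past the 1.5-fold limit. Counts of lower members are therefore high here for genes in general, and only the list values allow for this. Reg3g was 65.2-fold (36.4 to 131) and Reg3b 30.5-fold (24.1 to 39.2) lower, but the antimicrobial villus list had a value of 0.40 at percentile 88.08, with 5 members higher and 5 lower, since Duoxa2 was 6.68-fold (6.05 to 7.37) higher and Lypd8 7.69-fold (6.92 to 8.58) lower. It turned to -1.95 at a minimum of 50 expected UMIs and was 2.98 with all sections thinned to the shallowest total. Interferon-induced genes had 16 of 17 members lower and 1 higher (value -1.38). Isg15 was 11.7-fold (5.01 to 36.3), Igtp 10.3-fold (5.90 to 20.1) and Zbp1 6.00-fold (3.50 to 11.3) lower. Irgm1, with 0 UMIs against 433, was 11.5-fold lower against a floor of 3 UMIs. All 6 compared MHC class II genes were lower (value -0.83 at percentile 3.33). H2-Eb1 was 10.4-fold (5.25 to 24.1), H2-Ab1 3.53-fold (2.69 to 4.71), H2-DMa 3.18-fold (1.52 to 7.98) and Cd74 3.03-fold (2.56 to 3.62) lower, and 3 of the 6 met the rule of size. Proliferation genes had 13 of 17 lower (value -0.54). Cdk1 was 28.6-fold (9.75 to 139), Ccnb2 7.598-fold (3.23 to 23.5), Rrm2 6.49-fold (3.40 to 14.3) and Pcna 5.22-fold (3.58 to 7.95) lower. Enterocyte genes had 13 of 15 lower (value -0.93). Anpep was 11.8-fold (10.1 to 13.8), Lct 9.85-fold (7.88 to 12.5), Fabp1 6.92-fold (6.52 to 7.36) and Sis 6.86-fold (6.26 to 7.53) lower. Cholesterol synthesis and uptake genes had 19 of 22 lower (value -0.69). Pmvk was 9.85-fold (5.34 to 20.6), Dhcr7 8.51-fold (4.30 to 19.8) and Fdps 6.65-fold (3.70 to 13.4) lower. The xenobiotic metabolism list had a value of -0.35 at percentile 19.12, with 9 of 14 lower. Cyp3a25 was 12.1-fold (7.05 to 22.7), Cyp2b10 8.40-fold (5.54 to 13.4), Gstm3 5.56-fold (3.35 to 9.97) and Gsta1 2.68-fold (2.31 to 3.12) lower. The remaining genes furthest below were the inflammasome adaptor gene Pycard at 21.1-fold (11.5 to 44.1), Cyb5a at 13.03-fold (10.2 to 17.0), the aminopeptidase gene Enpep at 12.96-fold (9.99 to 17.1), Dmbt1 at 12.7-fold (10.4 to 15.7) and Barx2, with 0 UMIs against 509. Barx2 was 13.5-fold lower against a floor of 3 UMIs, with an exact log2 interval bound of -3.45. Of the LXR targets, Scd1 was 2.21-fold (2.18 to 2.25) and Abcg1 1.54-fold (1.24 to 1.91) higher, and Srebf1 was 2.73-fold (2.498 to 2.995), Abcg5 2.19-fold (1.78 to 2.72), Abcg8 1.71-fold (1.47 to 1.99) and Abca1 1.43-fold (1.24 to 1.67) lower. The median log2 ratio of all genes was itself -0.81. Relative to it the LXR sterol transport list had a value of 0.17 (percentile 74.99) and the lipogenic list 0.031 (61.63), so neither list lay below all genes.

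Of 6289 genes compared between the days on GW3965, 224 met the rule of size as higher at day 14 and 2530 as lower, with a median log2 ratio of -0.81 over all genes. TMM factors moved that median by 0.37 and gave 374 higher and 1476 lower, median-of-ratios factors moved it by 0.51 and gave 460 and 1170, totals without Gm42418, AY036118 and Lars2 moved it by 0.46 and gave 419 and 1271, and weighting each spot equally moved it by -0.13. Across 6253 genes the log2 day ratios of the 2 diets had a Pearson correlation of 0.78 and a Spearman correlation of 0.784, again across genes. By the rule of size 178 genes were higher at day 14 on both diets (15.3 for independent lists), 1304 were lower on both (625) and 6 went in opposite directions (227). In the 4 sections together 487 genes were at least 1.5-fold higher in both day 14 sections and 1945 lower, a split in which day, depth and the Gm42418 share run together.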

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

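Of the tests below, the one with totals that left out Gm42418, AY036118 and Lars2 used an alternative chosen after the data were seen. The limits of the tests were written before they were run, except those named next, but after the list values and gene counts of the whole sections were known, and the Gm42418 window was set after the data were seen. The comparison of lymphoid-led with other spots was added after the other tests. Its limit for MHC class II, its resampling and its comparison with the diet difference were written after values they rest on had been seen. The rule that picked out differences between the days was also set after the list values were seen.

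Several diet differences pointed in opposite directions at day 6 and day 14, and whether the 2 days differ was not tested, since each group held 1 section. Xenobiotic metabolism genes had a list value of -1.04 at day 6 and 1.03 at day 14. Antimicrobial villus genes had 0.43 and -0.84, and proliferation genes 0.64 and -0.44. By the rule of size 15 genes went in opposite directions, of which 7 are encoded by the mitochondrial genome. Of the others with the widest split, Reg3b had a log2 ratio of 4.67 at day 6 and -2.38 at day 14, Gstm1 -3.14 and 2.11, and Reg3g 4.25 and -1.97.

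Interferon-induced and MHC class II genes were higher on GW3965 at day 6, and lymphoid follicle tissue in that section may account for this. Without the spots of a region picked out by lymphoid genes, some of them its own leading genes, the interferon-induced list value was 0.77, from 0.78, and that of the 5 MHC class II members not leading the region 1.24, from 1.32. Both passed the limit written beforehand against that explanation, but the B cell list was still 0.86 (5 members, from 1.27 with 9), so lymphoid RNA was not fully removed. In the lymphoid-led over the other spots of the GW3965 section, 14 interferon-induced members had a value of 0.17 (-0.017 to 0.36 over resampled members) and 3 MHC class II members 1.54, and the diet difference outside those spots exceeded this by 0.59 (-0.002 to 0.83) for the former and by -0.25 for the latter. Within the regions led by Anxa10 and by smooth muscle genes the interferon values were 0.53 and 0.72, and those of MHC class II 2.22 and 1.004. Their enterocyte lists differed by -0.44 and 0.47, so neither region held like tissue on the 2 diets. The difference of 0.59 sets a ratio between diets against a ratio within 1 section, and its range reached 0, so it cannot decide the question. For both lists follicle tissue, a response to the agonist, a difference between these 2 mice and the stretch of gut under the section cannot be told apart.

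Many genes were set apart by day, 2432 of 6000, while the day 14 sections were shallower and held more Gm42418. The heat shock and dissociation list lay above the median of all genes (0.76 on standard diet, 0.97 on GW3965), but on GW3965 2 of its 8 members were higher and 2 lower. With all sections thinned to the shallowest total, 87.7% of those genes were still set apart, which passed the limit written beforehand against depth as the cause. Thinning keeps the expected ratios and adds counting noise only, so it cannot show what low capture per spot does to them. With totals that left out Gm42418, AY036118 and Lars2, 62.8% were still set apart. Among spots with a Gm42418 share of 5 to 15%, 57.0% of the 703 genes that could be compared still differed by 1.5-fold the same way on both diets. The 62.8% and 57.0% lay between the limits written beforehand, and the mean Gm42418 share of the chosen spots still ran from 6.34% at day 6 to 10.5% at day 14. Depth, RNA quality, the share taken by these genes, and a change of the tissue over the infection therefore cannot be told apart.

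Smooth muscle genes were lower on GW3965 at day 6, and less muscle layer in that section is a candidate explanation. Within the smooth muscle-led spots the 3 list members not leading the region had a value of -0.83, which passed the limit set beforehand against that explanation (-0.58). It was nevertheless left open afterwards, because only 3 members remained and because the same spots differed in their enterocyte list by 0.47, so they did not hold like tissue. Without the smooth muscle-led spots the list value was 0.11, but those spots were picked out by genes of the list itself, so this value cannot decide the question. Less muscle under the section and lower expression per muscle cell cannot be told apart, and at day 14 too few members remained for the same test.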

How the results depend on the processing

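Totals without Gm42418, AY036118 and Lars2, a count minimum on the mean CPM of both sections, and the unweighted neighbour graph were chosen after the data were seen; the other alternatives were planned. No paired analysis was made, because each group held 1 section and the sections carry no shared replicate numbers. No additive model of diet and day was fitted either, since its only residual would be the diet by day difference itself. Among list medians, 514 of 554 values under alternatives stayed close to the reported value, by a limit set after the values were seen, 34 moved and 6 turned. Part of this was fixed in advance, since list values are relative to the median of all genes. TMM factors, median-of-ratios factors and the altered totals shift a list and that median alike. They can move a list value only through which genes are compared. Of 2079 values of named genes, 1648 stayed within their counting interval, 420 moved and 11 turned. Of 156 counts of genes, 101 stayed within 1.5 times the reported count. A list with fewer than 3 compared members under an alternative gave no value there. Except where stated, the cause of a change was not tested. Depth limits what could be compared: 11021 genes at day 6 and 5439 at day 14.

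Counts of genes that met the rule of size changed as follows. For diet at day 6, the number higher was 124 with TMM factors, 112 with median-of-ratios factors, 109 with all sections thinned to the shallowest total and 385 without smooth muscle-led spots. It was 715 at 1.5-fold and 304 with no quadrant requirement, where the number lower was 262 and 184. For diet at day 14, TMM factors gave 86 higher and 62 lower, median-of-ratios factors 94 and 52, a 1.5-fold rule 78 and 570, and a minimum of 50 expected UMIs, by construction with fewer genes, 31 and 98. The number lower there was 425 with no quadrant requirement and 114 with totals without Gm42418, AY036118 and Lars2. For day on standard diet, the number higher was 954 at 1.5-fold and 383 at the minimum of 50. For day on GW3965, the numbers higher and lower were 374 and 1476 with TMM factors, 460 and 1170 with median-of-ratios factors, 122 and 1563 at the minimum of 50, and 419 and 1271 without Gm42418, AY036118 and Lars2, and 392 were higher at 1.5-fold. With the mean CPM in the count minimum they were 328 and 2165 on GW3965 and 762 and 1585 on standard diet. Of genes set apart by diet, the number lower was 8 with TMM factors, 11 with median-of-ratios factors, 29 with all sections thinned, 6 without smooth muscle-led spots and 11 at the minimum of 50; at 2-fold 5 were higher and 3 lower. The crossed split gave 14 and 44 with all sections thinned, and 3 and 6 with mitochondrial genes left out of the totals and of the compared genes.

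Some values turned. Without smooth muscle-led spots, diet at day 6 gave log2 ratios of 0.45 for Cnn1, 0.31 for Col1a2, 0.34 for Mmp3, 0.28 for Myh11, 0.71 for Snap25, 0.34 for Stmn2, 0.022 for Synm, 0.27 for Tagln and 0.67 for Timp1, and list values of 0.11 for smooth muscle, 0.87 for enteric neuron and glia, 0.12 for extracellular matrix and 0.048 for granuloma genes. Without those spots, day on standard diet gave 0.62 for Acta2 and 0.22 for the granuloma list. With the mean of CPM per spot, Scd1 turned to 0.026 for day on standard diet. The antimicrobial list turned to -1.95 for day on GW3965 at the minimum of 50, where fewer members were compared.

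Other list values moved. For diet at day 6, the mean of CPM per spot gave 0.87 for MHC class II, 0.024 for antimicrobial, 0.70 for B cell, 0.30 for proliferation, -1.18 for enteric neuron and -1.11 for granuloma genes, and the minimum of 50 gave -0.30 for the type 2 list. For diet at day 14, xenobiotic metabolism was 1.36 with all sections thinned and 1.62 with the mean CPM in the count minimum, and LXR sterol transport was 1.32 at the minimum of 50. For day on standard diet, the fibroblast list was 0.85 with median-of-ratios factors and with spots of at least 200 UMIs, 1.52 thinned, 2.40 without smooth muscle-led spots, 1.61 at the minimum of 50 and 0.86 without Gm42418, AY036118 and Lars2. There the tuft list was 2.57 thinned, the enterocyte list -1.68 with the mean of CPM per spot, the extracellular matrix and smooth muscle lists 2.39 and 1.08 without smooth muscle-led spots, and the granuloma, type 2 and villus tip lists -1.69, 2.08 and 0.60 at the minimum of 50. For day on GW3965, the type 2 list was 1.84 with TMM factors, 1.85 with median-of-ratios factors and without Gm42418, AY036118 and Lars2, 2.40 with spots of at least 200 UMIs, 2.08 thinned, 0.40 at the minimum of 50 and 2.13 with the mean CPM in the count minimum. There extracellular matrix was 1.53 with median-of-ratios factors, the antimicrobial list 2.98 thinned and 2.75 with the mean CPM in the count minimum, and Paneth 3.26 with the mean of CPM per spot.

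The smooth muscle-led share moved with the settings. In the standard section at day 6 it was 10.1% at resolution 1.0, 9.13% thinned to 100 UMIs, 11.5% thinned to 500 and 10.8% with the unweighted graph, and in the GW3965 section 4.17%, 4.83%, 4.17% and 3.05%. In the standard section at day 14 it was 7.67% at resolution 0.4, 12.9% thinned to 500 and 8.95% with the unweighted graph, and in the GW3965 section 6.45%, 8.14% and 6.99%. Regions led by Paneth genes appeared or vanished with these settings.

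Moran's I moved with the thinning depth, and thinning to 500 keeps only the deeper spots. LXR lipogenic targets had 0.018 in the standard day 6, 0.025 in the standard day 14 and 0.204 in the GW3965 day 14 section at 100 UMIs. At 500 UMIs they had 0.098 and 0.250 at day 6 and 0.079 and 0.567 at day 14, on standard diet and GW3965. Granuloma genes had 0.028 at 100 on GW3965 at day 6, and 0.017 and -0.010 on standard diet and GW3965 at day 14. At 500 they had 0.469 on standard diet at day 6, and 0.054 and 0.100 at day 14. B cell genes had 0.127 at 100 on standard diet at day 6, 0.046 and 0.030 at 100 at day 14, and -0.026 and 0.132 at 500 at day 14. Villus tip genes had 0.122 and 0.133 at 100 and 0.312 and 0.327 at 500 at day 6, and 0.189 and 0.510 on standard diet at day 14. Smooth muscle genes had 0.619 at 500 in the standard and 0.114 at 100 in the GW3965 section at day 14, and Paneth genes 0.110 and 0.194 at 500 in the GW3965 sections.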

Other observations

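The lists below were picked for mention after the values of all lists had been seen, and no further test was run. At day 6 tuft cell genes (list value -0.43, 3 of 10 members lower), fibroblast genes (-0.36, 2 of 12 lower and 1 higher) and T and NK cell genes (-0.46, 1 of 8 lower and 1 higher) lay below the median of all genes on GW3965. Enteroendocrine genes lay above it (0.27, 3 of 12 higher). Between the days, all 7 compared plasma cell genes were lower at day 14 on GW3965 (list value -0.90), the fetal-like and regenerating epithelium list had a value of 0.89 there, and endothelial genes were higher on standard diet (2.27, 2 of 3 compared members). The count of 7 is not adjusted for the median log2 ratio of all genes on GW3965, which was -0.81.

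Eosinophil, mast cell and type 2 cytokine genes were largely below the count minimum in these sections. No eosinophil gene of the fixed list was compared in any comparison, and at most 1 gene of type 2 lymphocyte cytokines and 2 of the mast cell list were, Mcpt1 and Mcpt2 at day 14. On GW3965 no mast cell gene reached the count minimum between the days. Within the smooth muscle-led spots at day 6, alternatively activated macrophage and granuloma genes had a list value of -1.80 and antimicrobial villus genes 1.56 on GW3965 over standard diet, with 103 and 309 spots. The mitochondrial share of UMIs was lower on GW3965 at day 6 (1.47% against 3.50%) and higher at day 14 (3.99% against 1.93%), the same directions as the xenobiotic metabolism list.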
